A study of Homo sapiens with 72 samples.

How the data were processed

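Gene expression was measured by sequencing of polyadenylated RNA in 72 libraries from 4 lines of HEK293 Flp-In T-REx cells, with 6 conditions per line and 3 replicates per condition. Per the labels' protocols, RNA was extracted with Qiagen RNeasy kits and libraries were made with NEBNext Ultra II Directional kits. Per the submitters' processing notes, reads were aligned to GRCh38 with STAR, quantified with RSEM, and turned into coverage tracks with deepTools 3.5.1. The deposited table, per the submitters' processing notes, holds unnormalised expected counts of reads per gene and library, and its values are whole numbers. No versions of STAR or RSEM and no release of the gene annotation are given there. The coverage tracks were not used. Symbols and GRCh38 coordinates of genes came from the deposited table, and exonic lengths from the reference annotation provided. Every library column of the table was matched to a sample by its label.

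Nothing in the labels says whether the 3 replicates of a group were separate cultures or irradiations, so the p-values measure only the spread between these samples. The labels name 1 clone of CSB_KO and 2 of STK19, so a clone cannot be told from a knockout in CSB_KO. WT is the only unedited line. A trait of WT, or one that edited lines share for another reason, cannot be told from a knockout in any comparison with WT. No group was pooled or left out. Samples labelled untreated serve as 0 h. Whether 4 h and 20 h count from irradiation or from addition of the inhibitor is not settled by the labels, and ATRi and DMSO were compared only at the same labelled time.

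The table held 19324 genes, 572 of them without a symbol. Genes were kept by filterByExpr of edgeR with the 24 groups, a minimum count of 10 and a minimum total of 15, which left 15470 genes and removed 3854. Library sizes ran from 36.5 to 212.9 M counts, scaled by the trimmed mean of M values (TMM) with factors from 0.857 to 1.125. All libraries entered 1 quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group and no covariate, so that all groups shared the trended spread. The 23 contrasts of 2 groups were knockout against WT at 0 h, 3 h, 4 h DMSO and 20 h DMSO against 0 h in each line, and ATRi against DMSO at 4 h and 20 h in each line. The 8 interaction contrasts set the change in CSB_KO, or the mean change in the 2 STK19 knockouts, against that in WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and calls with a fold change of at least 2 were counted as well. With libraries simulated on the WT samples at 20 h, 49 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold, 4-fold or by a factor of 0.5 were called, with 9 false calls among 15270 unchanged genes. The changed genes were drawn from those with a log2 CPM of at least 3. These rates therefore do not cover genes with lower counts, or comparisons in which most genes change.

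The comparisons, tests, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. ERCC6, STK19, ATR and CHEK1 were always to be named. For each family of comparisons over the lines, the 8 genes with the largest positive and the 8 with the largest negative mean log2 change were named, among genes with a symbol, a mean log2 CPM of at least 3 and a call of the same sign in all 4 lines. Where fewer than 8 qualified, genes called in at least 2 lines with the same sign in all 4 filled the places. For each knockout at 0 h it was the 5 largest each way, with no overlap between the libraries of the groups. For both STK19 knockouts together it was the 5 largest each way among genes called with the same sign in both, without a condition on overlap. For each interaction it was the 4 largest each way, and for each list up to 2 members that rose and 2 that fell. A few genes that this rule selects are not reported here. ADAMTS1 was named as the only call of its comparison, and some genes with very low counts were described by their counts. Names of genes with near-identical copies (SULT1A3, MAGED4B, F8A1, EOLA1, HSPA1B and replication histone genes) are uncertain, since reads may be shared between copies.

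The 24 lists were p53 targets, immediate early genes, replication histones, G1/S genes, mitotic (G2/M) genes, nucleotide excision repair, ATR checkpoint genes, homologous recombination and Fanconi genes, ATF4 targets, the unfolded protein response, heat shock, interferon-stimulated genes, NF-kB inflammation, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, RNA polymerase II transcription, neuronal genes, and markers of fibroblasts, blood, squamous epithelium and kidney tubule. They were written from general knowledge of human genes. Members that rose and fell were counted with the adjustment over all genes and with an adjustment over the list alone. Each list was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison, with an estimated correlation and with fry as alternatives.

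Genes moved by UV were defined as those called with at least a 2-fold change at 3 h against 0 h in WT, and the mean log2 CPM over each set (prior count 0.5) was taken per library. For gene length, the difference of log2 CPM from the mean of the line's 0 h libraries was regressed on log10 of the genomic span in each library. Both measures were compared by exact two-sided permutation of libraries within each line, 160000 assignments. Spans were available for all 15470 tested genes and exonic lengths for 15360 of them.

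Alternatives were DESeq2 1.42.0, scaling by relative log expression (RLE), no low-count filter, a block for the replicate number, only the libraries of a line, each STK19 knockout alone, a prior count of 5, other definitions of length and sets, and each library left out in turn. Fits with a library left out, the reassigned groupings below and the thinned libraries kept the trended dispersion and tested genes of the main fit and re-estimated the quasi-likelihood dispersion. A fit without WT at 0 h and 3 h replicate 1, and a thinning of the 20 h libraries to 1 depth, were added after the data were seen. Equal numbers did pair the libraries in part: every same-numbered pair had a correlation of deviations over 0.1 in 3 of 23 comparisons (3 h and 4 h DMSO in WT and ATRi at 4 h in STK19_KO1) with a filter on edgeR's average abundance, and in 5 with a filter on the mean log2 CPM. No label ties a replicate number to a day or batch, so the main fit had no block.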

Results

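Polyadenylated RNA was sequenced from HEK293 Flp-In T-REx cells, a human embryonic kidney line transformed with adenovirus DNA and carrying a site for targeted transgene insertion. The 4 lines were unedited cells (WT), a knockout of CSB (CSB_KO), and 2 knockouts of STK19 (STK19_KO1 and STK19_KO2). CSB, the product of ERCC6, binds RNA polymerase II stalled at DNA lesions and starts transcription-coupled repair, a pathway to which STK19 has also been assigned. Each line had 6 conditions with 3 libraries each, 72 libraries in 24 groups. The conditions were untreated cells (0 h), cells 3 h after ultraviolet (UV) irradiation, and irradiated cells at 4 h and at 20 h in the solvent DMSO or in 3 µM VE-821, an inhibitor of the DNA damage checkpoint kinase ATR (ATRi). The labels leave the origin of the times open, since the series design counts hours from irradiation and the sample descriptions count them from addition of the inhibitor. The UV dose is not given in the sources used here. No unirradiated group at later times, or with DMSO or ATRi, was analysed here. Changes against 0 h therefore do not separate UV from time in culture or solvent. Changes with ATRi cannot be tied to irradiation. The study asked how inhibition of ATR alters transcription after UV.

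The libraries held between 36.5 and 212.9 M counts each (M, 10 to the power of 6), with a median of 56.3 M. In WT the range was 46.2 to 77.3 M at 0 h and 37.2 to 58.1 M at 20 h with ATRi, and the deepest group was STK19_KO1 at 20 h with ATRi, at 65.1 to 212.9 M. Of 19324 genes in the table, 15470 were tested. Replicates of a group differed by more than sampling noise in all 72 pairs (chi-square per gene of at least 3.64), and libraries of different groups were not compared in this way. For 5 libraries both of their pairs had a value over 20, so they lay apart from the other 2 of their groups: replicate 1 of WT at 0 h, at 3 h and at 4 h in DMSO, replicate 3 of STK19_KO1 at 3 h and replicate 1 of STK19_KO1 at 4 h with ATRi. Levels are given as mean counts per M (CPM) ± SD with n = 3, fold changes as log2 ± standard error, and adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. All values are relative abundances, since no external standard set the total amount of RNA.

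The targeted genes were examined first. ERCC6 (ENSG00000225830, GRCh38 chromosome 10, 49454168 to 49539538) stood at 6.97 ± 0.611 CPM in CSB_KO at 0 h and at 23.5 ± 0.473 CPM in WT, a log2 fold change of -1.77 ± 0.08 (edgeR, adjusted p = 4.01e-27). In STK19_KO1, ERCC6 stood at 23.9 ± 0.570 CPM and did not differ from WT by the test (edgeR, adjusted p = 0.794). STK19 (ENSG00000204344, chromosome 6, 31971091 to 31982821) stood at 19.0 ± 1.07 CPM in WT, 17.5 ± 0.587 CPM in STK19_KO1 and 17.1 ± 0.862 CPM in STK19_KO2. Neither difference in STK19 passed the test (edgeR, adjusted p = 0.187 and 0.0882). The RNA level of STK19 therefore did not check the labels of its knockouts, since an edit that ends the protein can leave the transcript in place.

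**Figure D1:**
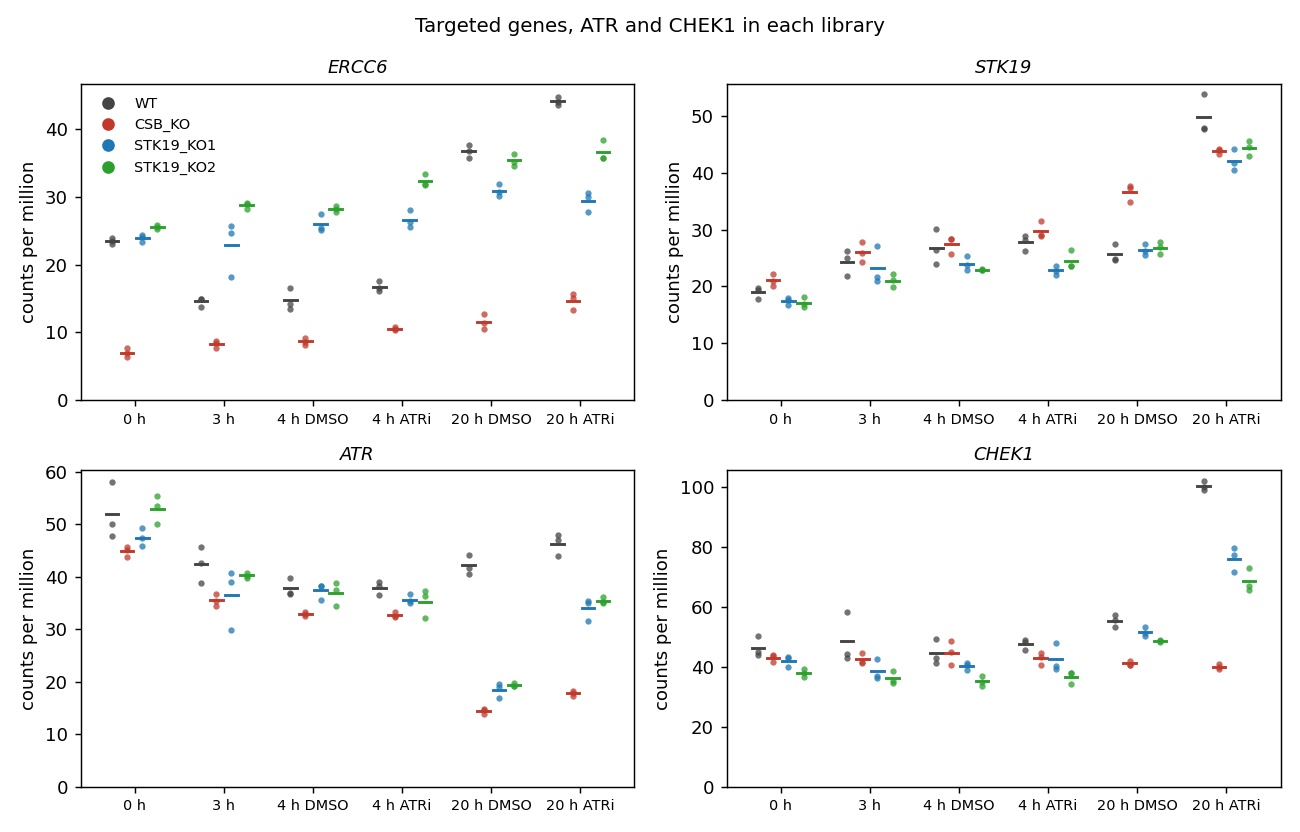
Abundance of ERCC6, STK19, ATR and CHEK1 in counts per M over the 6 conditions, one point per library and one colour per line, with a line through the mean of 3 libraries. At 0 h the mean for ERCC6 was 6.97 in CSB_KO and 23.5 in WT, while STK19 stood at 19.0 in WT and 17.5 and 17.1 in its knockouts.

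Before irradiation the edited lines already differed from WT in many genes. ZNF320, a zinc finger gene, was close to absent in WT (0.105 ± 0.0385 CPM) and stood at 12.4 ± 0.984 CPM in CSB_KO, with log2 fold changes of 6.79 ± 0.20 in CSB_KO, 7.02 ± 0.20 in STK19_KO1 and 6.66 ± 0.21 in STK19_KO2. LCP1, an actin-bundling protein of blood cells, rose by 2.93 ± 0.05, 3.32 ± 0.05 and 3.11 ± 0.05 on the log2 scale in these lines. With WT as the only unedited line, changes shared by the edited lines cannot be told from a trait of WT. In CSB_KO the largest other increases were in PCDH19, a protocadherin (43.1 ± 0.190 against 1.46 ± 0.444 CPM), AMOT (3.08 ± 0.07) and ULK2, an autophagy kinase (2.88 ± 0.11). The largest decreases there beside ERCC6 were in RAC3 (-1.85 ± 0.10), GSTP1, a glutathione transferase (-1.72 ± 0.08), PTBP2, a splicing regulator (-1.57 ± 0.08), and the translation factor EIF1AX (-1.52 ± 0.08). CEBPE, a myeloid transcription factor, and PYCR1, an enzyme of proline synthesis, were nearly lost in both STK19 knockouts. CEBPE had 3774 to 8384 counts per library in WT at 0 h, 0 to 3 in STK19_KO1 and 0 to 11 in STK19_KO2, and PYCR1 had 1593 to 3448, 0 to 3 and 0 to 4.

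STK19_KO1 also had lower TSPO (-5.31 ± 0.28), LDOC1 (-5.002 ± 0.19) and PXDN (-4.74 ± 0.11), and higher AMOT (2.94 ± 0.07), STS (2.13 ± 0.09) and CELSR3 (2.11 ± 0.12). STK19_KO2 had lower ETV4 (-3.36 ± 0.10) and higher ULK2 (3.30 ± 0.11). Genes changed in both STK19 knockouts included RAI2 (1.67 ± 0.08 and 1.90 ± 0.08), TMEM145 (1.90 ± 0.10 and 1.83 ± 0.10), OAS3, an interferon-induced sensor of viral RNA (-4.48 ± 0.15 and -3.48 ± 0.13), and SPRY4, an inhibitor of growth factor signalling (-2.90 ± 0.10 and -3.36 ± 0.10). Genes of cholesterol synthesis were lower in every edited line. Of 23 measured, 0 rose and 18 fell in CSB_KO, 0 and 15 in STK19_KO1, and 1 and 16 in STK19_KO2. The numbers adjusted over the list alone were 0 and 18, 0 and 15, and 1 and 19, and camera gave adjusted p = 4.43e-11, 4.95e-06 and 1.54e-07. SQLE, the squalene epoxidase, changed by -0.87, -0.98 and -1.01 on the log2 scale. Interferon-stimulated genes were lower in the STK19 knockouts, with 2 of 22 that rose and 9 that fell in STK19_KO1 and 4 and 9 in STK19_KO2, the same numbers adjusted over the list alone (camera, adjusted p = 1.52e-05 and 0.00354). BST2, an antiviral membrane protein, changed by -3.63 in STK19_KO2.

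In all, 5381 genes differed from WT at 0 h in CSB_KO (2952 higher, 2429 lower), 7540 in STK19_KO1 (4564 and 2976) and 7323 in STK19_KO2 (4114 and 3209). The numbers that differed by at least 2-fold were 608, 1105 and 1014. Smaller list results in STK19_KO1 were p53 targets (19 of 28 rose and 2 fell, 19 and 3 adjusted over the list alone; camera, adjusted p = 0.0199), and nucleotide excision repair and ATF4 targets (camera, adjusted p = 0.0406 for both, adjusted p = 0.0559 and 0.0752 with an estimated correlation). The unfolded protein response in CSB_KO had 3 of 16 that rose and 9 that fell, the same numbers adjusted over the list alone (camera, adjusted p = 0.0243, adjusted p = 0.157 with an estimated correlation). STK19_KO2 had lower ATF4 targets (camera, adjusted p = 0.0158), while camera gave adjusted p = 0.0458 for immediate early, NF-kB and neuronal genes, with adjusted p = 0.541, 0.145 and 0.1 with an estimated correlation. These comparisons shared the 3 untreated WT libraries. The fold changes of STK19_KO1 and STK19_KO2 had a Pearson correlation of 0.660 across genes (genes are not independent replicates), against 0.497 for simulated unchanged groups, and a covariance of 0.561 against 0.0867. Of their calls, 3014 rose and 1761 fell in both, against 1214 and 617 for independent lists. With CSB_KO the correlations were 0.535 and 0.499, the covariances 0.404 and 0.329, the genes that rose in both 2080 (871 for independent lists) and 1977 (785), and those that fell 1289 (467) and 1331 (504). The simulated groups shared 0 calls in 10 simulations. The 3 controls were not split between the comparisons, so part of the excess may come from the shared libraries.

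At 3 h after UV, the genes with the largest increases in all 4 lines were short and those with the largest decreases were long. HEXIM1 (chromosome 17, 45148475 to 45152099), which encodes an inhibitor of the elongation factor P-TEFb, stood at 577 ± 57.4 CPM in WT against 79.1 ± 2.42 CPM at 0 h, a log2 fold change of 2.87 ± 0.05 (edgeR, adjusted p = 1.01e-48), and rose by 2.44 in CSB_KO, 2.81 in STK19_KO1 and 3.09 in STK19_KO2. The growth factor HBEGF rose by 2.97 ± 0.05 in WT (52.1 ± 2.47 against 6.63 ± 0.686 CPM), and the transcription factor genes SNAI1 and FOSB by 3.49 ± 0.12 and 3.07 ± 0.09. VASN (3.21), IER5L (3.38), SERTAD1 (3.20) and the Notch ligand DLL4 (3.23) completed the 8 largest increases, with values between 2.00 and 3.31 in the edited lines. TGFBR3 (chromosome 1, 91680343 to 91906335), a receptor of transforming growth factor beta, fell from 31.6 ± 2.19 to 4.78 ± 0.331 CPM in WT, a log2 fold change of -2.73 ± 0.08 (edgeR, adjusted p = 5.12e-35), and changed by -2.66, -2.33 and -2.19 in CSB_KO, STK19_KO1 and STK19_KO2. The Wnt pathway ubiquitin ligase ZNRF3 changed by -2.86 ± 0.11 in WT, and the receptor gene BMPR1A by -2.46 ± 0.08. LHFPL2 (-2.71), LRCH1 (-2.54), PHLPP1 (-2.41) and PLCL2 (-2.42) were other large decreases. These 7 genes spanned 174 to 288 kb, and the 8 that rose spanned up to 13.8 kb.

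Immediate early genes led the lists at 3 h. In WT 18 of 24 rose and 2 fell (the same numbers adjusted over the list alone; camera, adjusted p = 2.63e-15), and 18 to 21 rose in each edited line (camera, adjusted p = 5.42e-16, 2.02e-13 and 2.00e-37 in CSB_KO, STK19_KO1 and STK19_KO2). CCN2 rose by 2.99 in WT, while MYC fell by 1.74. Targets of ATF4, the effector of the integrated stress response, rose in 14 of 20 and fell in 3 in WT (the same adjusted over the list alone; camera, adjusted p = 1.75e-05), with DDIT3 at 2.17. All 40 ribosomal protein genes rose in WT, with a median log2 change of 0.66 (camera, adjusted p = 1.27e-11, but adjusted p = 0.148 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 33 of 34 (33 adjusted over the list alone; camera, adjusted p = 6.80e-07, but adjusted p = 0.300 with an estimated correlation). G1/S genes rose in 23 of 30 and fell in 4 (the same adjusted over the list alone; camera, adjusted p = 0.000199), with CCNE1 at 1.14 and E2F1 at 0.77. Mitotic genes fell in 16 of 28 and rose in 4 (the same adjusted over the list alone; camera, adjusted p = 0.0396, adjusted p = 0.408 with an estimated correlation), with KIF23 at -1.17 and CENPA at -1.12. Histone, unfolded protein response and RNA polymerase II genes also ranked higher (camera, adjusted p = 0.0175, 0.00584 and 0.00136), with adjusted p = 0.148, 0.128 and 0.0580 with an estimated correlation. The share of counts from the mitochondrial genome was 4.27 ± 0.0717% in WT at 3 h and 3.30 ± 0.182% at 0 h (n = 3).

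At 3 h, 9653 genes had changed in WT (5192 rose, 4461 fell), 9485 in CSB_KO (4949 and 4536), 9369 in STK19_KO1 (4628 and 4741) and 8918 in STK19_KO2 (4504 and 4414). The numbers at 2-fold or more were 1951, 1774, 1826 and 1583. Across lines, 2860 genes rose and 3149 fell in all 4. The fold changes of WT and CSB_KO had a Spearman correlation of 0.768 across genes, which are not independent replicates. Without replicate 1 of WT at 0 h and 3 h, 9099 genes changed in WT, an alternative chosen after seeing the data, and 8449 changed in STK19_KO1 without replicate 3 at 3 h.

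At 4 h in DMSO, FOSB rose by 3.47 ± 0.09 in WT (22.1 ± 1.09 against 1.97 ± 0.120 CPM; edgeR, adjusted p = 3.35e-38), and CCN2, a matricellular growth regulator, by 3.11 ± 0.07. SNAI1 (3.82), VASN (3.58), IER5L (3.72), SERTAD1 (3.30), HEXIM1 (3.22) and HBEGF (3.13) were the other largest increases. PLCL2, an inactive relative of phospholipase C, changed by -3.18 ± 0.09 (3.25 ± 0.0469 against 29.4 ± 0.434 CPM) and LHFPL2 by -3.04 ± 0.08. TGFBR3 (-2.96), BMPR1A (-2.88), ZNRF3 (-2.77), PHLPP1 (-2.64) and LRCH1 (-2.51) followed. The numbers of genes changed against 0 h were 10254 in WT (5408 rose, 4846 fell), 9860 in CSB_KO (5194 and 4666), 8944 in STK19_KO1 (4309 and 4635) and 9496 in STK19_KO2 (4892 and 4604), and 2921 rose and 3347 fell in all 4 lines. Immediate early genes rose in 18 of 24 in WT and fell in 2, the same adjusted over the list alone (camera, adjusted p = 1.57e-14). ATF4 targets rose in 14 of 20 (15 adjusted over the list alone) and G1/S genes in 23 of 30 (23 adjusted over the list alone), with 2 and 4 that fell (camera, adjusted p = 6.92e-06 and 5.71e-05). All 40 ribosomal protein genes and all 34 of oxidative phosphorylation rose (40 and 34 adjusted over the list alone; camera, adjusted p = 4.52e-09 and 1.78e-05, but adjusted p = 0.215 and 0.357 with an estimated correlation). Mitotic genes fell in 17 of 28 and rose in 1 (the same adjusted over the list alone; camera, adjusted p = 0.00241, adjusted p = 0.215 with an estimated correlation).

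At 20 h in DMSO the changes in WT were less like those in the edited lines than at 3 h. Their Spearman correlations across genes were 0.518 to 0.645, against 0.721 to 0.768 at 3 h. The most genes changed in CSB_KO. HBEGF, which stood at 24.8 ± 0.454 CPM in WT against 6.63 ± 0.686 CPM at 0 h (log2 fold change 1.90 ± 0.05; edgeR, adjusted p = 1.35e-37), reached 159 ± 6.05 CPM in CSB_KO (4.58 ± 0.05) and rose by 3.20 in STK19_KO1 and 3.64 in STK19_KO2. The glutamate receptor gene GRM2 rose by 2.48 ± 0.20 in WT and 5.44 in CSB_KO, and the neurotrophin receptor gene NGFR by 2.26 ± 0.13 and 4.25. HAP1 (2.14), IER5L (2.03), SP6 (2.15), SERTAD1 (1.75) and the glycolytic ALDOC (1.74) were the other largest increases in WT by the mean over lines, at 3.09 to 4.92 in the edited lines. GPC6, a glypican gene that spans 1181 kb, fell from 13.1 ± 0.932 to 0.590 ± 0.140 CPM in WT (-4.36 ± 0.13; edgeR, adjusted p = 2.14e-35) and changed by -1.89 ± 0.10 in CSB_KO. GPHN, which encodes the synaptic scaffold gephyrin, changed by -3.08 ± 0.08 in WT and -3.95 ± 0.09 in CSB_KO. CDH4 (-4.43), PRKG1 (-3.75), KCNQ5 (-3.10), PTPRG (-3.00), ARL15 (-2.63) and KLF12 (-1.92) were the other largest decreases in WT by that mean. All 8 genes that fell most spanned 427 to 1308 kb. ATR (ENSG00000175054, chromosome 3, 142449007 to 142578733) changed by -0.30 ± 0.07 in WT, -1.64 ± 0.07 in CSB_KO, -1.36 in STK19_KO1 and -1.45 in STK19_KO2. Genes of 100 to 300 kb, a range that includes ATR, had median log2 changes of -0.29, -1.15, -0.78 and -0.87 in the same order.

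Targets of p53 rose together at 20 h. In WT 25 of 28 rose and 0 fell (the same adjusted over the list alone; camera, adjusted p = 4.42e-12), and 20, 24 and 20 rose in CSB_KO, STK19_KO1 and STK19_KO2 (camera, adjusted p = 8.69e-05, 1.64e-08 and 6.74e-06). GADD45A, a growth arrest gene, rose by 1.71, 3.33, 2.23 and 2.92 in the order WT, CSB_KO, STK19_KO1, STK19_KO2, and TP53INP1 by 1.54, 1.37, 1.91 and 1.21. ATF4 targets rose in 17 of 20 in WT and fell in 1, 2 adjusted over the list alone (camera, adjusted p = 7.23e-17), with CHAC1 at 2.42 and DDIT3 at 1.89. NF-kB genes rose in 9 of 15 in WT and 0 fell, the same adjusted over the list alone (camera, adjusted p = 0.00112), with CXCL8 at 2.84 and TNF at 2.305. Genes of cholesterol synthesis fell in 16 of 23 in WT and 0 rose, the same adjusted over the list alone (camera, adjusted p = 5.87e-07), with INSIG1 at -1.42. Of immediate early genes 17 of 24 rose in WT and 22 in CSB_KO (17 and 22 adjusted over the list alone; camera, adjusted p = 8.08e-08 and 1.40e-14). Mitochondrially encoded genes fell in 12 of 13 in WT (the same adjusted over the list alone; camera, adjusted p = 0.00218, adjusted p = 0.507 with an estimated correlation), where their share of counts was 2.35 ± 0.368% against 3.30 ± 0.182% at 0 h.

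In CSB_KO at 20 h, all 40 ribosomal protein genes rose with a median log2 change of 1.22 (40 adjusted over the list alone; camera, adjusted p = 5.81e-13, but adjusted p = 0.154 with an estimated correlation). All genes with a genomic span of up to 10 kb had a median of 0.73 there, and no list test took span into account. Genes of oxidative phosphorylation rose in 33 of 34 there (33 adjusted over the list alone; camera, adjusted p = 6.11e-07, adjusted p = 0.274 with an estimated correlation), and RNA polymerase II transcription genes in 23 of 30 with 5 that fell (the same adjusted over the list alone; camera, adjusted p = 2.07e-05), among them HEXIM1 at 3.42 and POLR2A at 2.53. Homologous recombination and Fanconi genes fell in 17 of 24 and rose in 5 in CSB_KO (the same adjusted over the list alone; camera, adjusted p = 0.0274, adjusted p = 0.271 with an estimated correlation), with FANCC at -2.38 and XRCC2 at -1.35. At 20 h in DMSO, 8570 genes had changed in WT (4638 rose, 3932 fell), 12201 in CSB_KO (5929 and 6272), 10695 in STK19_KO1 (4971 and 5724) and 11079 in STK19_KO2 (5232 and 5847). The numbers at 2-fold or more were 1780, 5745, 3059 and 3616, and 2368 genes rose and 2514 fell in all 4 lines. Across genes, which are not independent replicates, the Spearman correlation of fold changes was 0.518 between WT and CSB_KO and 0.870 between the STK19 knockouts.

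**Figure D2:**
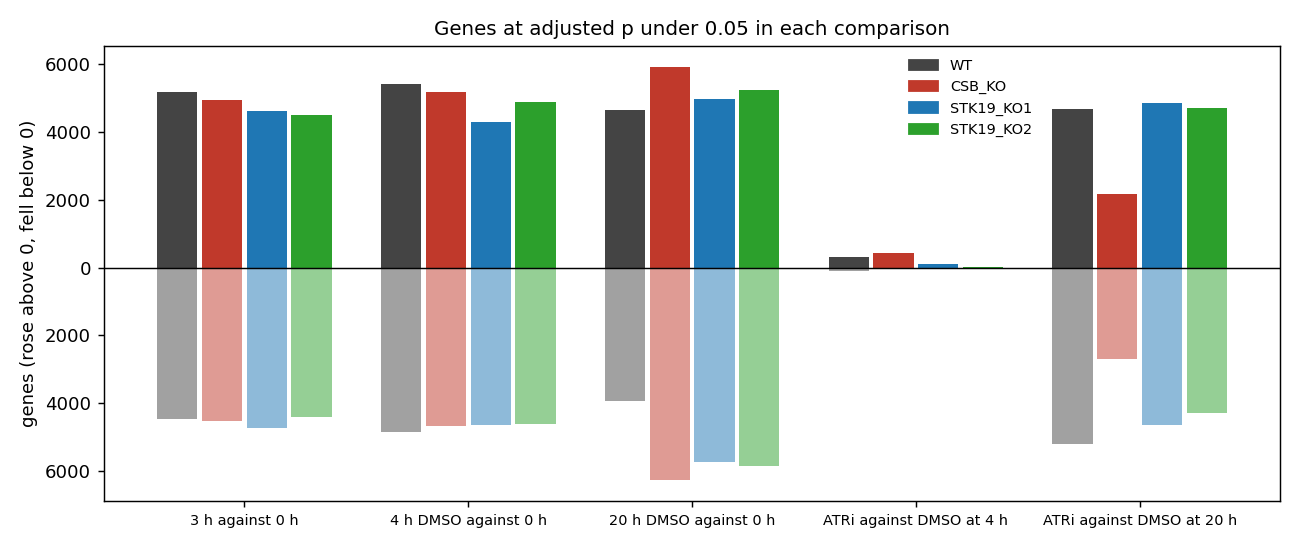
Number of genes that rose (bars above 0) or fell (bars below 0) at adjusted p under 0.05 in each comparison, one colour per line. At 20 h in DMSO the numbers that changed ran from 8570 in WT to 12201 in CSB_KO, while ATRi against DMSO gave 34 to 460 genes at 4 h and 4876 to 9885 at 20 h.

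UV lesions block elongation, so fold changes were set against the genomic span of each gene. At 3 h in WT the 3124 genes of up to 10 kb had a median log2 change of 0.40, the 4256 genes of 10 to 30 kb 0.25, the 4975 genes of 30 to 100 kb -0.09, the 2475 genes of 100 to 300 kb -0.41 and the 640 genes over 300 kb -0.43. At 20 h in DMSO the medians in WT were 0.21, 0.17, 0.04, -0.29 and -1.62, and in CSB_KO 0.73, 0.43, -0.25, -1.15 and -1.45. Of the genes of 100 to 300 kb, 53.4% fell in WT, 77.4% in CSB_KO, 74.5% in STK19_KO1 and 75.8% in STK19_KO2 at 20 h. Of those over 300 kb, these shares were 83.9%, 77.3%, 82.8% and 86.4%. The slope of the change on log10 span differed between 3 h and 0 h by -0.605 over the 4 lines together, and between 20 h DMSO and 0 h by -0.890, with exact two-sided permutation p = 1.25e-05 for each, the smallest that the 160000 assignments within lines can give. At 20 h the difference was -0.65 in WT, -1.22 in CSB_KO, -0.80 in STK19_KO1 and -0.89 in STK19_KO2. A single line with 3 libraries against 3 cannot give an exact p under 0.1. The Spearman correlation of fold change with span across genes was -0.501 in WT at 3 h, -0.418 in WT at 20 h and -0.561 in CSB_KO at 20 h, and with exonic length -0.457, -0.209 and -0.412. The list tests took no account of span, so list results against 0 h were not separated from this trend.

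**Figure D3:**
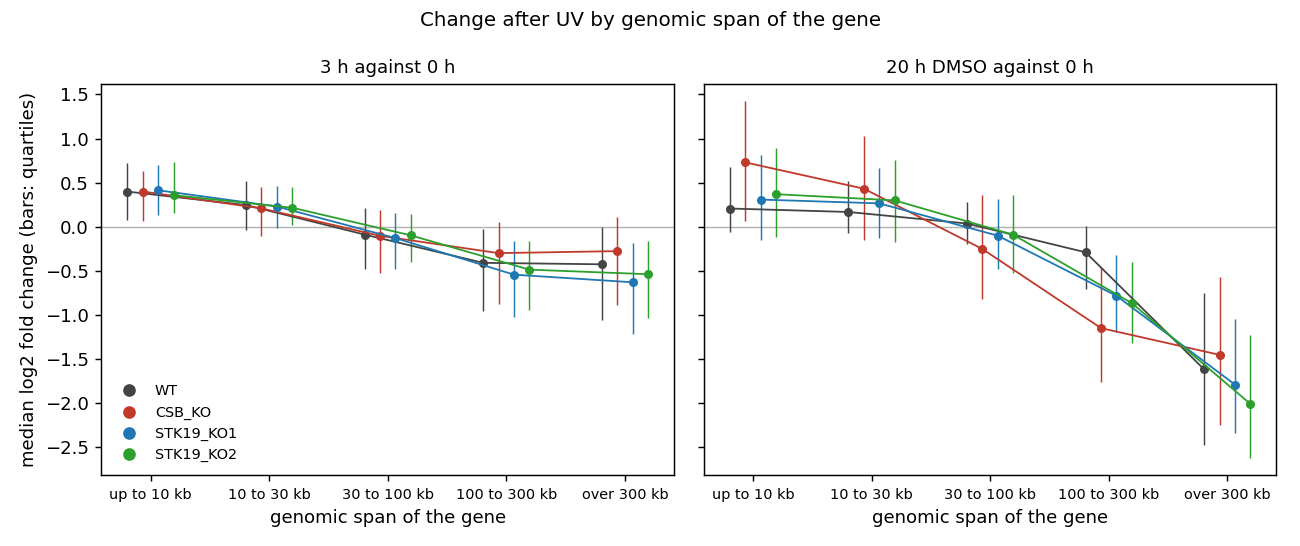
Median log2 fold change against 0 h in bins of gene span (kb), with bars from the lower to the upper quartile of genes and one colour per line, for 3 h and for 20 h in DMSO. Genes over 300 kb had medians of -0.43 at 3 h and -1.62 at 20 h in WT, and genes of up to 10 kb had 0.40 and 0.21.

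The changes against 0 h were compared between lines with interaction terms. At 3 h, 1513 genes responded otherwise in CSB_KO than in WT (229 with a higher and 1284 with a lower change) and 4201 in the mean of the STK19 knockouts (1559 and 2642). The early gene EGR1 had a higher log2 change than in WT, by 0.96 ± 0.09 in CSB_KO and 1.59 ± 0.08 in the STK19 knockouts, and SPRY4 by 1.86 ± 0.11 in the latter. ID2, an inhibitor of helix-loop-helix factors, responded by -1.26 ± 0.09 and -1.12 ± 0.08 relative to WT. At 20 h in DMSO the numbers were 10400 in CSB_KO (4785 higher, 5615 lower) and 8578 in the STK19 knockouts (3526 and 5052). SNAI1 differed from WT by 3.41 ± 0.18 and the secreted pentraxin gene NPTX2 by 3.00 ± 0.09 in CSB_KO, and NGFR by 2.10 ± 0.16 in the STK19 knockouts. ROBO1, an axon guidance receptor gene, differed by -3.11 ± 0.10 and -2.21 ± 0.09, and ATR by -1.34 ± 0.10 and -1.11 ± 0.08 (edgeR, adjusted p = 2.24e-18 and 2.06e-17). Genes with the span of ATR also fell more in the edited lines than in WT, and the ATR difference was not separated from this. All 40 ribosomal protein genes had a higher change in CSB_KO than in WT at 20 h (40 adjusted over the list alone; camera, adjusted p = 6.16e-17, but adjusted p = 0.0896 with an estimated correlation). Homologous recombination and Fanconi genes had a lower change in 18 of 24 (18 adjusted over the list alone; camera, adjusted p = 0.000427, adjusted p = 0.0756 with an estimated correlation). All 13 mitochondrially encoded genes had a higher change there (13 adjusted over the list alone; camera, adjusted p = 0.00558, adjusted p = 0.559 with an estimated correlation), with shares of counts at 20 h of 3.93 ± 0.449% in CSB_KO and 2.35 ± 0.368% in WT. The 3 h count for CSB_KO was 2270 without replicate 2 of WT at 3 h, and that for the STK19 knockouts was 2592 with STK19_KO1 alone and 3986 with STK19_KO2 alone.

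At 4 h, cells in ATRi differed little from cells in DMSO, and the genes that rose in all 4 lines included early response genes. EGR1 stood at 69.9 ± 2.78 CPM with ATRi and 48.1 ± 3.11 CPM with DMSO in WT, a log2 fold change of 0.54 ± 0.06 (edgeR, adjusted p = 3.48e-08), and rose by 0.27 in CSB_KO, 0.84 in STK19_KO1 and 0.73 in STK19_KO2. GADD45B, a stress gene, rose by 0.46 ± 0.08 in WT and TXNIP, which binds thioredoxin, by 0.54 ± 0.07. TRIB1 (0.45), the histone gene H2BC26 (0.48), FOS (0.26), EIF5 (0.19) and COX19 (0.19) also rose in every line, although COX19 lost its call in STK19_KO2 with the replicate number as a block (edgeR, adjusted p = 0.0532). ID1, a target of BMP signalling, was the 1 gene that fell in all 4 lines, from 34.3 ± 3.56 to 25.8 ± 2.35 CPM in WT (-0.41 ± 0.10; edgeR, adjusted p = 0.00998). ID3 fell in STK19_KO1 and STK19_KO2 (-0.34 and -0.39), THAP10 in WT and STK19_KO1 (-0.28 in both) and PARP1, a sensor of DNA breaks, in WT and CSB_KO (-0.11 in both), with the same sign in the other lines. Immediate early genes rose in 6 of 24 in WT, 2 in CSB_KO, 10 in STK19_KO1 and 8 in STK19_KO2, and 0 fell. Adjusted over the list alone the numbers that rose were 10, 4, 14 and 11, with 1 that fell in WT and in STK19_KO2. Camera gave adjusted p = 1.55e-12, 0.00139, 8.55e-44 and 5.87e-37 for this list, with adjusted p = 0.386 with an estimated correlation in CSB_KO. ATF4 targets rose in 4 of 20 in WT (5 adjusted over the list alone; camera, adjusted p = 2.33e-07), with CHAC1 at 0.83.

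In CSB_KO, 12 of 13 mitochondrially encoded genes rose with ATRi at 4 h, with a median log2 change of 0.68 (13 adjusted over the list alone; camera, adjusted p = 3.42e-26). Their share of counts was 3.92 ± 0.308% with ATRi and 2.399 ± 0.222% with DMSO. The DMSO value was the lowest of the line's groups, with 3.34% at 0 h and 3.01% at 3 h. In WT, STK19_KO1 and STK19_KO2 the medians were -0.22, -0.29 and -0.20 with 0 of 13 members past the test in each (camera, adjusted p = 0.000427, 9.67e-09 and 6.04e-05, but adjusted p = 0.339, 0.138 and 0.404 with an estimated correlation). In STK19_KO1 the share of counts was 2.01%, 3.10% and 3.497% in the 3 ATRi libraries and 3.31%, 3.32% and 3.72% with DMSO. The lowest value came from ATRi replicate 1, which lay apart. Against WT, 11 of the 13 had a higher change in CSB_KO (13 adjusted over the list alone; camera, adjusted p = 7.61e-25). Replication histone genes in CSB_KO had 0 of 31 past the test, with camera at adjusted p = 0.0489 and at 0.0681 with the replicate number as a block, and adjusted p = 0.386 with an estimated correlation. In STK19_KO1 the markers of squamous epithelium (0 rose, 1 of 9 fell, the same adjusted over the list alone) and of kidney tubule (0 of 7 past the test) ranked lower, with camera at adjusted p = 0.00408 and 0.00858.

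At 4 h, 411 genes differed between ATRi and DMSO in WT (314 higher, 97 lower), 460 in CSB_KO (417 and 43), 140 in STK19_KO1 (120 and 20) and 34 in STK19_KO2 (30 and 4), of which 10, 8, 5 and 1 differed by at least 2-fold. In all 4 lines 9 rose and 1 fell. The interaction called 495 genes in CSB_KO (360 higher, 135 lower), led by PSPN (1.25 ± 0.15) and AOC3 (1.25 ± 0.12), and 1 in the STK19 knockouts, ADAMTS1 (0.24 ± 0.04). For the STK19 knockouts, 831 genes had an unadjusted p under 0.05, and DESeq2 called 12. The WT count fell to between 197 and 247 without any of ATRi replicates 1, 2 and 3 or DMSO replicates 2 and 3, and to 17 when only WT libraries were fitted. The count was 286 in CSB_KO without DMSO replicate 2, 65 and 79 in STK19_KO1 without ATRi replicate 1 or DMSO replicate 2, and 19 to 22 in STK19_KO2 without ATRi replicate 2 or 3 or DMSO replicate 1 or 3, and fits to the libraries of each line gave 865, 72 and 83.

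At 20 h, ATRi changed a large part of the measured genes. ATF3, a stress-induced transcription factor gene, stood at 458 ± 9.87 CPM with ATRi and 115 ± 2.89 CPM with DMSO in WT (log2 fold change 1.99 ± 0.04; edgeR, adjusted p = 6.74e-45) and at 605 ± 15.05 against 315 ± 12.8 CPM in CSB_KO (0.94 ± 0.04). GADD45A rose by 2.01 ± 0.05 in WT, 0.96 ± 0.05 in CSB_KO, 2.17 in STK19_KO1 and 1.83 in STK19_KO2. The tumour suppressor gene RASSF1 rose by 2.22 ± 0.07 in WT (166 ± 3.77 against 35.7 ± 2.59 CPM) and 1.08 ± 0.07 in CSB_KO. DHRS2 (2.60 ± 0.11), OVGP1 (2.54), TNFAIP3, a feedback inhibitor of NF-kB (2.49 ± 0.09), DUSP8 (2.305) and C11orf96 (1.89) were the other largest increases. METTL7A changed by -2.36 ± 0.09 in WT and -0.53 in CSB_KO, and the homeobox genes HOXA13 and HOXB13 by -2.12 ± 0.08 and -1.86 in WT. BTN3A2 (-2.04), VANGL2 (-1.84), RASSF5 (-1.63), B4GAT1 (-1.48) and HPS6 (-1.20) were the other largest decreases. CHEK1 (ENSG00000149554, chromosome 11, 125625163 to 125676255), the checkpoint kinase phosphorylated by ATR, stood at 100.3 ± 1.56 against 55.3 ± 2.09 CPM in WT (0.86 ± 0.07; edgeR, adjusted p = 1.72e-15), at 39.9 ± 0.859 against 41.1 ± 0.777 CPM in CSB_KO (adjusted p = 0.716), and rose by 0.56 ± 0.07 and 0.49 ± 0.07 in the STK19 knockouts. ATR stood at 46.3 ± 2.11 against 42.2 ± 1.83 CPM in WT (edgeR, adjusted p = 0.0698, and 0.0487 with the replicate number as a block). It rose by 0.31 ± 0.07 in CSB_KO (17.9 ± 0.463 against 14.4 ± 0.523 CPM), 0.88 ± 0.07 in STK19_KO1 and 0.87 ± 0.07 in STK19_KO2, while STK19 rose by 0.96 ± 0.07 in WT.

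With ATRi at 20 h, G1/S genes rose in 27 of 30 in WT, 25 in STK19_KO1 and 24 in STK19_KO2 (camera, adjusted p = 8.17e-19, 1.77e-09 and 3.57e-06), and in CSB_KO 2 rose and 7 fell (camera, adjusted p = 0.124). Adjusted over the list alone, 27, 25 and 25 rose, and in CSB_KO 2 rose and 7 fell. The helicase genes MCM7 and MCM3 rose by 0.97 and 0.79 in WT and by 0.17 and 0.29 in CSB_KO. Immediate early genes rose in 20 of 24 in WT (21 adjusted over the list alone; camera, adjusted p = 1.17e-07), with KLF6 at 1.32. Homologous recombination and Fanconi genes rose in 16 of 24 and fell in 6 in WT (the same adjusted over the list alone; camera, adjusted p = 7.91e-05), with BARD1 at 0.96 and BRIP1 at 0.89. NF-kB genes rose in 9 of 15 and fell in 2 in WT, 3 adjusted over the list alone (camera, adjusted p = 0.000358), with CXCL8 at 3.27. Heat shock genes fell in 11 of 15 in WT, 10 in CSB_KO, 12 in STK19_KO1 and 11 in STK19_KO2 (11, 12, 12 and 11 adjusted over the list alone; camera, adjusted p = 0.000298, 1.50e-12, 7.93e-08 and 2.74e-06, with adjusted p = 0.0526 with an estimated correlation in WT). HSPA8, the constitutive HSP70, changed by -1.25 in WT and -1.06 in CSB_KO. HSPA1B, whose reads may be shared with its near-identical copy, changed by -1.85 in WT. Mitotic genes fell in 19 of 28 and rose in 4 in WT (camera, adjusted p = 0.00565, adjusted p = 0.246 with an estimated correlation), with the cyclin gene CCNB1 at -0.95.

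The remaining lists in WT at 20 h with ATRi were as follows. ATR checkpoint genes rose in 9 of 18 and fell in 5 (camera, adjusted p = 0.0185, adjusted p = 0.190 with an estimated correlation), with ATRIP, the partner of ATR, at 0.86. RNA polymerase II genes rose in 18 of 30 and fell in 4 (camera, adjusted p = 0.00451, adjusted p = 0.0710 with an estimated correlation), with HEXIM1 at 0.63. Camera did not call p53 targets (9 of 28 rose, 5 fell; adjusted p = 0.128), nucleotide excision repair genes (17 of 26 rose, 7 fell; adjusted p = 0.106), genes of cholesterol synthesis (9 of 23 rose, 13 fell; adjusted p = 0.106) or of hypoxia and glycolysis (13 of 20 rose, 4 fell; adjusted p = 0.128). It did not call interferon-stimulated genes (5 of 22 rose, 10 fell; adjusted p = 0.222), the unfolded protein response (3 of 16 rose, 6 fell; adjusted p = 0.788), ribosomal proteins (12 of 40 rose, 3 fell; adjusted p = 0.617) or oxidative phosphorylation (4 of 34 rose, 9 fell; adjusted p = 0.515). Replication histones (7 of 31 rose, 1 fell; adjusted p = 0.730) had a median of 0.21 and a mean of -0.08, and ATF4 targets (8 of 20 rose, 5 fell; adjusted p = 0.962) a median of 0.06 and a mean of -0.08, with camera pointing up for the former and down for the latter. Of 13 mitochondrially encoded genes none passed the test (adjusted p = 0.962), and neuronal genes rose in 9 of 20 and fell in 5 (adjusted p = 0.468). Markers of other cell types were not called by camera: fibroblast (0 of 9 rose, 4 fell; adjusted p = 0.222), blood (1 of 6 rose, 0 fell; adjusted p = 0.788), squamous epithelium (0 of 9 rose, 4 fell; adjusted p = 0.617) and kidney tubule (1 of 7 rose, 3 fell; adjusted p = 0.0898). Adjusted over the list alone, the numbers that rose or fell differed from these by at most 3 members in any list.

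At 20 h, 9885 genes differed between ATRi and DMSO in WT (4672 higher, 5213 lower), 4876 in CSB_KO (2175 and 2701), 9517 in STK19_KO1 (4867 and 4650) and 9002 in STK19_KO2 (4720 and 4282). The numbers at 2-fold or more were 2015, 220, 1693 and 1341, and 1263 genes rose and 1358 fell in all 4 lines. The interaction called 7985 genes in CSB_KO (3823 higher, 4162 lower) and 6334 in the STK19 knockouts (3206 and 3128). At 2-fold or more, 1122 were higher and 390 lower in CSB_KO and 542 and 51 in the STK19 knockouts. CHEK1 responded less than in WT, by -0.90 ± 0.11 in CSB_KO and -0.33 ± 0.09 in the STK19 knockouts (edgeR, adjusted p = 1.67e-10 and 0.00218). EXO1, a nuclease of mismatch repair, and ORC1, a subunit of the origin recognition complex, differed by -1.89 ± 0.07 and -1.85 ± 0.07 in CSB_KO. KLF12 differed by 2.41 ± 0.21 in CSB_KO and 1.96 ± 0.17 in the STK19 knockouts. G1/S genes had a lower response than in WT in 28 of 30 in CSB_KO and 23 in the STK19 knockouts (28 and 24 adjusted over the list alone; camera, adjusted p = 1.97e-27 and 2.07e-11). NF-kB and RNA polymerase II genes had a lower response in 9 of 15 and 21 of 30 in CSB_KO (9 and 22 adjusted over the list alone; camera, adjusted p = 0.000924 and 5.65e-05). Across genes, which are not independent replicates, the fold changes of WT and CSB_KO had a Spearman correlation of 0.270, and those of the STK19 knockouts 0.815.

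The genes moved by UV at 3 h in WT at 2-fold or more, 1152 lowered and 799 raised, were then followed in the ATRi and DMSO libraries, none of which had been used to define them. At 20 h the lowered genes differed between ATRi and DMSO by -0.233 in mean log2 CPM over the 4 lines together, and the raised genes by 0.545, each with an exact two-sided permutation p = 1.25e-05, the smallest possible. The difference for lowered genes was -0.47 in WT, -0.10 in CSB_KO and -0.18 in each STK19 knockout, and for raised genes 0.33, 0.38, 0.79 and 0.69 in WT, CSB_KO, STK19_KO1 and STK19_KO2. At 4 h the lowered genes differed by 0.0663 (exact permutation p = 0.00025) and the raised genes by 0.00725 (exact permutation p = 0.857), with -0.22 in WT and 0.30 in CSB_KO. For the raised genes at 4 h the difference was 0.0440 among genes with a mean log2 CPM of at least 3 (exact permutation p = 0.0172), -0.0151 for the set called in all 4 lines and -0.00561 to 0.0180 with a library left out. Camera called the raised genes lower in WT (21 rose, 38 fell; adjusted p = 9.39e-08) and higher in CSB_KO (75 rose, 1 fell; adjusted p = 1.55e-14) at 4 h. In WT at 20 h, 655 of the lowered genes were lower with ATRi than with DMSO and 178 higher (camera, adjusted p = 1.21e-07), and 299 of the raised genes were higher and 51 lower (camera, adjusted p = 6.96e-05). For the lowered genes in CSB_KO, STK19_KO1 and STK19_KO2 camera gave adjusted p = 0.000863, 0.00435 and 0.00865, which became p = 0.212, 0.281 and 0.322 with an estimated correlation. The slope on gene span differed between ATRi and DMSO by 0.00890 at 4 h and -0.0245 at 20 h (exact permutation p = 0.538 and 0.206). At 20 h the slope in WT was -0.789 ± 0.0376 with ATRi and -0.654 ± 0.0390 with DMSO. The libraries did not overlap, and the difference was -0.135. In CSB_KO, STK19_KO1 and STK19_KO2 the differences were 0.0104, 0.0101 and 0.0170, and the lines were not tested against each other. Genes over 300 kb had a median log2 change with ATRi at 20 h of -0.35 in WT and 0.09, 0.06 and 0.09 in the other lines. On exonic length the 20 h difference was -0.157 (exact permutation p = 7.5e-05), and among genes with a mean log2 CPM of at least 3 the span slope differed by 0.000248.

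**Figure D4:**
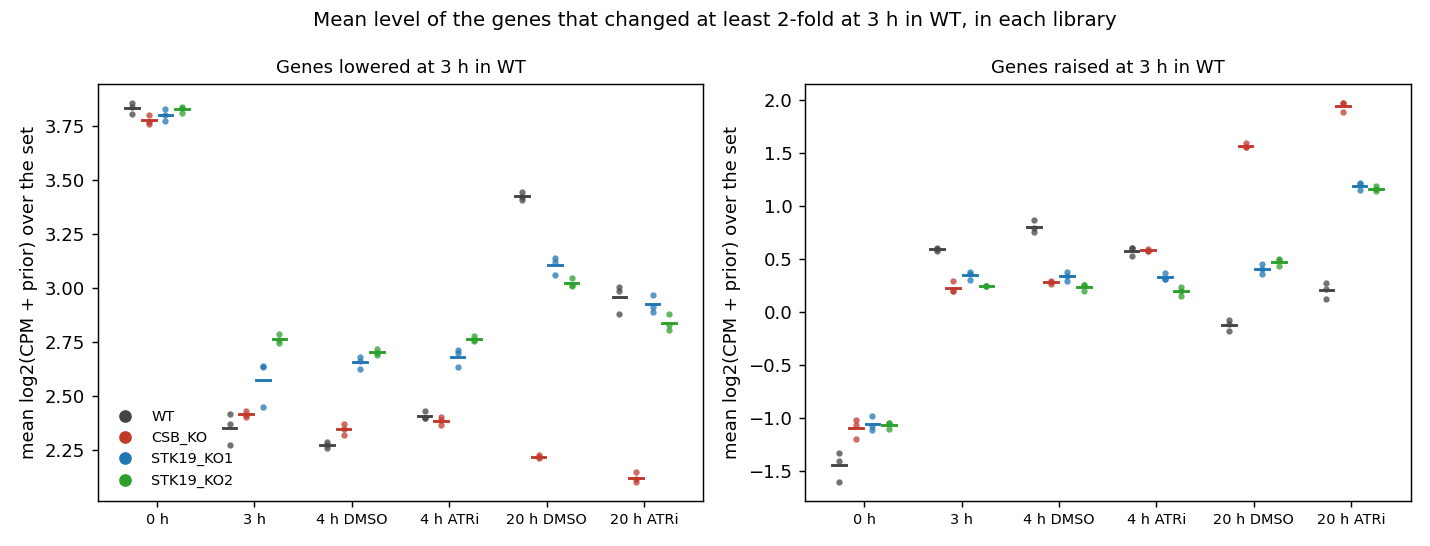
Mean log2 CPM per library over the genes lowered and the genes raised by UV at 3 h in WT, by condition, with one point per library, one colour per line and lines through the means of 3 libraries. Between DMSO and ATRi at 20 h the lowered genes differed by -0.47 and the raised genes by 0.33 in WT.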

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

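Most results below were flagged because a response in an edited line differed from that in WT by an interaction test. For 2 others, the ATRi libraries of CSB_KO and WT lay on opposite sides of the mean of their DMSO libraries, without a test between them. All tests of depth, spread, single libraries and scaling given below were chosen after the results were seen, with only the prediction for depth written before its test was run. The interaction tests called 1513 genes at 3 h in CSB_KO and 4201 in the STK19 knockouts, 10400 and 8578 at 20 h in DMSO, 495 and 1 for ATRi against DMSO at 4 h, and 7985 and 6334 at 20 h. When the libraries were regrouped in 100 ways, the real grouping included, 55 and 15 gave at least as many calls at 3 h, 5 and 4 at 20 h in DMSO, 20 and 48 for ATRi at 4 h, and 11 and 10 for ATRi at 20 h. The highest counts among the other groupings were 10571 and 7223, 11921 and 9790, 6584 and 7573, and 11220 and 8350. The other groupings mix lines, times and treatments that differ and so carry real changes, a structure of the samples, and a share of 0.05 or more does not show that a count arose by chance. The share was under 0.05 only for the STK19 knockouts at 20 h in DMSO, where another grouping reached 9790 calls against 8578. As the groupings are not alike, this share decides no more than the others, and the comparison gave no verdict on chance for any count.

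In CSB_KO, 4876 genes changed with ATRi at 20 h, fewer than in the other lines (9885, 9517 and 9002), a comparison of counts without a test of its own. The gap to WT was smaller in fits to the libraries of each line alone, which have a spread of their own. They gave 6168 calls in CSB_KO and 8759, 9386 and 9969 in WT, STK19_KO1 and STK19_KO2. Unequal depth was tested as an explanation by thinning all 20 h libraries to 1 total, and the CSB_KO count was at most 0.529756 of the lowest other count. The 20 h libraries of CSB_KO held 38.8 to 133.7 M counts with ATRi and 39.8 to 76.6 M with DMSO. Those of WT held 37.2 to 58.1 M and 41.1 to 137.2 M, so against WT thinning could hardly have come out otherwise. A larger spread in CSB_KO was addressed by comparing it with each other line over genes called with 1 sign in the remaining 2 lines. The median change in CSB_KO was at most 0.367345 of that in the other line, also with any 20 h library of either line left out. This compared sizes of change and measured no spread. The main fit shared its spread per gene over all groups, so a larger spread in CSB_KO could not cost this line alone its calls. This signed median also falls where genes respond in another direction in CSB_KO, so alone it does not separate a smaller from a different response. The median absolute log2 change over all genes, which ignores direction, was 0.19 in CSB_KO. It was 0.44 in WT, 0.38 in STK19_KO1 and 0.35 in STK19_KO2. Thinning did not remove the lower count, and the spread within CSB_KO was not measured. By the median absolute change, the response to the inhibitor was smaller in this line. With 1 CSB_KO clone, a property of the clone could give the same result, and the line had already changed most by 20 h in DMSO.

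Mitochondrially encoded transcripts were higher with ATRi at 4 h in CSB_KO, where the share of counts from the mitochondrial genome was 3.92 ± 0.308% against 2.399 ± 0.222% (n = 3). In CSB_KO this share was 3.34% at 0 h and 3.01% at 3 h, so part of the difference lies in a low DMSO group. In WT, STK19_KO1 and STK19_KO2 the share at 4 h in DMSO was above that at 0 h (4.71% against 3.30%, 3.45% against 2.89% and 3.83% against 2.88%). A single library was tested as an explanation, and the lowest median log2 change with any of the 6 left out was 0.609754. The shares did not overlap (lowest 3.59% with ATRi, highest 2.61% with DMSO), so the difference did not rest on 1 library. Leaving 1 out could therefore not have removed it. The scaling of the libraries was tested with RLE factors, which gave 0.667988. The mean TMM factors were already close (0.99 with ATRi, 0.983 with DMSO), so this test could hardly have come out otherwise and decides nothing. The share of counts is computed without these factors. The share was also higher with ATRi at 20 h in CSB_KO (5.11 ± 0.447% against 3.93 ± 0.449%), and a difference in extraction or handling between the samples could not be excluded, since it was not tested.

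For CSB_KO against WT at 3 h, genes with a higher response were EGR1 (0.96), ERCC6 (0.95), MFSD4B (0.80) and ARC (0.71), and genes with a lower response BCL6 (-1.51), ID2 (-1.26), EFNB2 (-1.20) and SULT1A3 (-1.19), all in log2. In the STK19 knockouts these were SPRY4 (1.86), EGR1 (1.59), ZNF345 (1.05) and ETV5 (1.05), and PHLDA1 (-1.19), DLL4 (-1.13) and ID2 (-1.12), and ERCC6 differed by 0.74. At 20 h in DMSO, CSB_KO differed most in SNAI1 (3.41), NPTX2 (3.00), GRM2 (2.96) and EHBP1L1 (2.91), and in ZNF608 (-3.18), ADGRL2 (-3.16), ROBO1 (-3.11) and KDM6A (-2.96). The STK19 knockouts differed most in NGFR (2.10), SPRY4 (2.05), PHLDA2 (2.00) and TNFSF9 (1.82), and in PYCR1 (-2.22), ROBO1 (-2.21), KMT2C (-1.995) and MUC16 (-1.99). ATR differed by -1.34 and -1.11, not separated from the larger fall of genes of its span in these lines.

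For ATRi against DMSO at 4 h, CSB_KO differed most in PSPN (1.25), AOC3 (1.25), KRBA2 (1.199) and EHBP1L1 (1.19), and in ZNRF1 (-0.63), TWIST1 (-0.62), TBC1D12 (-0.60) and PET117 (-0.57), and the STK19 knockouts in ADAMTS1 (0.24). At 20 h, CSB_KO differed most in NYNRIN (2.81), KLF12 (2.41), ITGA2 (2.35) and LPIN3 (2.32), and in H4C14 (-2.13), DHRS2 (-2.09), EXO1 (-1.89) and ORC1 (-1.85). The STK19 knockouts differed most in PYCR1 (2.68), KLF12 (1.96), AHNAK (1.87) and ZFHX3 (1.66), and in MAGED4B (-1.36), EOLA1 (-1.18), F8A1 (-1.17) and PET117 (-1.16). CHEK1 differed by -0.90 and -0.33, STK19 by -0.70 and -0.26, and ATR by 0.74 in the STK19 knockouts. Both values for PYCR1 rest on counts near 0 in the STK19 knockouts.

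In 2 cases every ATRi library at 4 h lay on one side of the mean of the DMSO libraries in CSB_KO and on the other side in WT. The genes raised by UV differed by 0.525 between CSB_KO and WT in mean log2 CPM, and the slope on gene span by -0.0796. Between the libraries neither difference was tested. For the slope in WT, the ATRi and DMSO libraries overlapped (-0.718 ± 0.0273 against -0.766 ± 0.0658), while in CSB_KO they did not. Across genes, camera called a higher response of the raised genes in CSB_KO than in WT (96 higher, 2 lower; adjusted p = 6.00e-21, p = 3.4e-14 with an estimated correlation), while the difference in slope was not tested.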

How the results depend on the processing

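Of the main summary values under all alternatives, 455 kept their label, 14 were stronger, 19 weaker and 3 reversed, and of the values for named genes 5829 were unchanged, 18 stronger, 151 weaker and 27 reversed. For lists 542 values kept their label, 154 were weaker and 0 reversed. The smallest counts, those for ATRi against DMSO at 4 h, depended most on the setting, and the cause was not tested. The only interaction call of the STK19 knockouts at 4 h became 12 with DESeq2, 2 with RLE, 0 without the filter, 4 with the replicate block, 0 with STK19_KO1 alone and 0 to 5 with a library left out. Fits to the libraries of a line gave 17 calls in WT, 865 in CSB_KO, 72 in STK19_KO1 and 83 in STK19_KO2, and leaving out a library gave 197 to 471, 286 to 333, 65 to 135 and 19 to 28. DESeq2 called 511 in WT, of which 65.9% were higher against 76.4% in edgeR. The 3 h interaction had 1129 to 2270 calls in CSB_KO with a library left out and 2592 for STK19_KO1 and 3986 for STK19_KO2 alone. Over all comparisons and lists, camera called 232 lists, 95 with an estimated correlation and 488 with fry. The replicate block gave 9913 calls at 3 h and 10494 at 4 h DMSO in WT and 539 and 174 for ATRi at 4 h in WT and STK19_KO1, and moved no count of genes by over 1.5 times but the one of 4. Under the block, COX19 with ATRi at 4 h in STK19_KO2 lost its call (edgeR, adjusted p = 0.0532), as did the histone list named with its result, ID3 with ATRi at 4 h in CSB_KO (adjusted p = 0.0110) and ATR with ATRi at 20 h in WT (adjusted p = 0.0487) gained one, and no other named gene or list changed its call. Without WT at 0 h and 3 h replicate 1, the WT counts were 9099 at 3 h, 10042 at 4 h and 8505 at 20 h in DMSO, the knockouts at 0 h had 5560, 7412 and 7402, and the interactions 1171, 3223, 10604 and 8881.

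For the genes raised by UV, the 4 h difference with ATRi was 0.0440 at a mean log2 CPM of at least 3 (permutation p = 0.0172), -0.0151 for the set called in all 4 lines (permutation p = 0.204) and -0.00561 to 0.0180 with a library left out. The difference in span slope at 20 h with ATRi was 0.000248 at a mean log2 CPM of at least 3 and -0.157 on exonic length. The cause was not tested.

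No named gene called in the main fit reversed. With RLE and DESeq2, CHEK1 at 20 h DMSO in CSB_KO became 0.0247 and 0.0246, and ATR with ATRi at 4 h in WT -0.00515 and -0.00524 (-0.0226 to 0.0358 with a library left out). ATR with ATRi at 4 h in CSB_KO became 0.00544 without the filter, 0.000153 with only that line and -0.0177 to 0.00393 with a library left out. Without WT replicate 1 at 0 h and 3 h, CHEK1 in WT became -0.0279 at 3 h and 0.00233 at 4 h DMSO (-0.0910 to 0.140 and -0.141 to 0.00481 with a library left out). Leaving out a library also gave, for CHEK1 in CSB_KO, -0.0448 to 0.00660 at 3 h, -0.00275 to 0.123 at 4 h DMSO and -0.121 to 0.00487 with ATRi at 4 h. In STK19_KO1 it gave -0.152 to 0.0856 for ERCC6 at 3 h, and with ATRi at 4 h -0.000977 to 0.0786 for ERCC6 and -0.0135 to 0.131 for CHEK1. It gave -0.0289 to 0.114 for ATR in STK19_KO2 against WT at 0 h and -0.0265 to 0.142 for STK19 with ATRi at 4 h in WT. No scaling moved the median change of all genes by more than 0.1.

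Groups of 3 against 3 allow 10 splits, too few for a share under 0.05. The highest count among the other splits was 6070 against 9653 at 3 h in WT, 3596 against 9369 at 3 h in STK19_KO1, 5003 against 10254 at 4 h DMSO in WT and 959 against 8570 at 20 h DMSO in WT. For the knockouts at 0 h it was 7, 167 and 84, and elsewhere at most 8.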

Other observations

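Neuronal genes moved in both directions at 20 h in DMSO. In WT 7 of 20 rose and 7 fell (the same adjusted over the list alone; camera, adjusted p = 0.833). The neurofilament gene NEFH rose by 1.72 in WT, 4.08 in CSB_KO, 2.11 in STK19_KO1 and 2.62 in STK19_KO2 on the log2 scale, and the tubulin gene TUBB3 by 1.67, 2.60, 2.66 and 2.92. NRXN3, which encodes a synaptic adhesion protein, changed by -2.96, -3.08, -3.33 and -3.78, and NCAM1, a cell adhesion gene, by -2.18, -1.50, -2.38 and -2.63. HEK293 cells are known to express a number of neuronal genes. The genomic spans of these genes were not taken into account.

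Interferon-stimulated genes were also split. With ATRi at 20 h, ISG15, a ubiquitin-like modifier, rose by 0.62, 0.96, 1.46 and 1.71 in WT, CSB_KO, STK19_KO1 and STK19_KO2, while the antiviral genes IFIT1 (-3.01, -1.30, -2.79 and -1.98) and IFIT2 (-2.58, -1.15, -2.01 and -1.67) fell. The secreted granin gene CHGA rose by 1.82, 0.42, 1.93 and 1.36.

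It was a hypothesis of this re-analysis that the low values of the longest genes at 20 h in WT reflect their span rather than their abundance or their exonic length. Genes over 300 kb had a median log2 change lower by 1.33 than genes of 100 to 300 kb. Low expression as an explanation was tested among genes with a mean log2 CPM of at least 3, where the difference was -1.16791 (309 and 1663 genes). Exonic length was tested within its middle range, where the difference was -1.23405 (124 and 644 genes). Neither explanation accounted for the difference, and both predictions had been written before the tests. The result is consistent with a loss of transcripts that scales with the distance polymerases must travel, but RNA abundance may also fall through decay, and nascent RNA was not measured.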
